A study of Homo sapiens with 24 samples.

How the data were processed

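Poly(A)-selected RNA was measured in SBC-3, a human small cell lung cancer cell line, 72 h after reverse transfection of small interfering RNAs (siRNAs) or antisense oligonucleotides (ASOs) at 10 nM, per the labels' protocols. The 24 libraries form 8 groups of 3. The siRNA arm holds a control siRNA (siCtrl), siSFPQ-2 and siSFPQ-3 against SFPQ, and siNONO-3 and siNONO-4 against NONO. The ASO arm holds a control ASO (ASO-Ctrl) and a pair of ASOs against NEAT1, ASO-NEAT1-1047 and ASO-NEAT1-1473. Nothing in the labels says that the replicates of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

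The authors deposited whole-number read counts per Ensembl gene, 60605 genes in each library, with no normalization. Per the submitters' processing notes, the tools were cutadapt 4.2, STAR 2.7.5a, featureCounts from Subread 2.0.3 and DESeq2 1.38.1, with genome build hg38. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes that overlap another gene, antisense genes, pseudogenes and members of near-identical families, such as the core histone genes, are therefore uncertain. Total counts per library ran from 4243196 to 14886353, and 38046 genes had a read in at least 1 library. No molecular identifiers that would tell PCR copies apart are mentioned in the sources used here, so intervals and floors on low counts cover counting error only.

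From the deposited counts, fold changes were computed with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, expression filter by group, robust fit). One fit held all 24 libraries, so that the groups shared 1 estimate of the spread, and 15869 genes were tested. TMM factors ran from 0.949 to 1.045. A target's effect was the mean of its 2 reagents minus the control of its arm. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and "rose" and "fell" are used of called genes. Unless stated otherwise, adjusted p-values are edgeR's, changes of single genes are log2 fold changes, given in part with their standard error (SE), and CPM are counts scaled to a common library total with TMM factors. Each reagent alone, the difference between targets, the difference between the reagents of a target and ASO-Ctrl minus siCtrl were tested in the same fit. DESeq2 1.42.0 served as an alternative. Comparisons of a single value per library used exact 2-sided permutation tests over the 9 libraries of a target, which have 84 splits and a smallest p of 0.0119.

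Gene names came from a table of gene identifiers, which matched 60463 genes, and GENCODE annotation gave a biotype for 58337 genes and the GC content of transcripts. Coordinates are those of the deposited files. Before the data were examined, 23 gene lists were fixed, along with the contrasts and their tests, the rule for named genes and all alternatives but the length threshold named below. The further tests in the closing section are dated there. The lists were paraspeckle proteins, microRNA processing machinery, noncoding and protein-coding microRNA host genes, p53 target genes, interferon-stimulated genes, NF-kB target genes, integrated stress response genes, endoplasmic reticulum chaperones, S-phase genes, mitosis genes, double-strand break repair genes, cholesterol synthesis genes, glycolysis and hypoxia genes, neuroendocrine genes, non-neuroendocrine and mesenchymal genes, extracellular matrix and adhesion genes, synaptic and axon guidance genes, markers of other cell types, mitochondrially encoded mRNAs, polyadenylation factors, nuclear exosome and decay factors, and core histone genes. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 69 tests of the 3 targets, and again with the correlation estimated from the data. Counts of members were also adjusted over the list alone.

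The named genes were SFPQ, NONO, NEAT1 and PSPC1; the 10 largest rises and falls per target among genes called with both reagents and in their mean, at a mean of at least 5 CPM in at least 1 group and with a regular symbol; up to 2 risen and 2 fallen members of each list; the 3 largest in each direction of each difference between targets; and noncoding host genes over the same CPM that were not called. MIR17HG, FTX, MIRLET7IHG, MIR497HG, H19 for NONO, CDKN1A, MDM2 and FAS were named outside this rule, after their values were seen. A fold against a group without reads was computed against a floor of 3 counts over that group.

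The effect of gene length was measured per library as the median log2 ratio to the control of genes spanning over 100 kb minus that of the other genes. A threshold of 300 kb was added after the data were seen. The real control libraries stayed the reference in every split, so their own values lay near 0 by construction. For this measure the permutation tests are therefore not exact and lean towards a small p. The alternatives were other scalings, DESeq2, no expression filter or 1 CPM in 3 libraries, each arm or target fitted alone, the replicate number as a block, each library left out in turn, a 2-fold minimum, other length thresholds and matching on expression in 10 groups. The fit was tested on simulated counts of 15866 genes with 200 genes changed per target. For SFPQ it recovered 51.5%, 83.6% and 97% of genes changed by 0.5, 1 and 2 on the log2 scale, for NONO 53%, 76.1% and 95.5%, and for NEAT1 48.5%, 80.6% and 97%. False calls were 3.73%, 5.66% and 3.82% of the calls. The changed genes were drawn from those at a mean of at least 1 CPM, with rises and falls balanced, in independent simulated libraries. The rates therefore leave out genes of lower counts. They do not cover a change as broad as that after SFPQ knockdown or a structure by replicate number. Replicates of a group were compared by the chi-square of their counts per degree of freedom, which ran from 3.21 to 12.49, so no pair looked like 1 library deposited again. Effects that share control libraries were set beside 20 simulations of unchanged groups.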

Results

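RNA sequencing was used to ask how the paraspeckle components SFPQ and NONO, which are RNA-binding proteins, and NEAT1, the long noncoding RNA on which paraspeckles assemble, shape gene expression in SBC-3 cells. The study is concerned with the transcription and stability of primary microRNAs, the long precursors of microRNAs, so host genes of microRNAs are described with the other gene groups. Each of the 8 groups had 3 libraries. Total counts ran from 9999025 to 13525528 in siCtrl, 4243196 to 9747514 in siSFPQ-2, 8483440 to 8846636 in siSFPQ-3, 9451335 to 10660126 in siNONO-3 and 9239632 to 10341311 in siNONO-4. In the ASO arm they ran from 9717221 to 14810746 in ASO-Ctrl, 10162388 to 14886353 in ASO-NEAT1-1047 and 10768393 to 13193403 in ASO-NEAT1-1473. The first principal component of log2 CPM held 66.19% of the variance and set the 6 siSFPQ libraries apart from all others.

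SFPQ RNA (chromosome 1, 35176378 to 35193145, hg38) fell from 1223 ± 40.2 CPM (SD, n = 3) in siCtrl to 207.6 ± 47.3 with siSFPQ-2 and 222.5 ± 27.3 with siSFPQ-3. The log2 fold change was -2.51 (SE 0.09, adjusted p = 5.89e-19), or 17.5% of the control. NONO RNA (chromosome X, 71254814 to 71301522, overlapping ZMYM3) fell from 399.1 ± 14.9 CPM to 69.23 ± 9.3 with siNONO-3 and 70.07 ± 5.06 with siNONO-4, by 2.52 on the log2 scale (SE 0.07, adjusted p = 5.11e-20). NEAT1 RNA (chromosome 11, 65422774 to 65445540) stood at 297.2 ± 85.8 CPM in ASO-Ctrl, 297.4 ± 47 in ASO-NEAT1-1047 and 205.9 ± 25.4 in ASO-NEAT1-1473. Its log2 fold change was -0.26 (95% interval -0.693 to 0.167, adjusted p = 1), with 0.003 for the first ASO and -0.53 (-1.031 to -0.025, adjusted p = 1) for the second. Unadjusted, the edgeR p was 0.0408 for the second ASO and 0.0398 for the difference between the ASOs. The mean over both ASOs ran from -0.451 without ASO-Ctrl replicate 1 to -0.032 without ASO-Ctrl replicate 3. NEAT1 climbed with the replicate number in ASO-Ctrl (215.8, 288.9 and 386.8 CPM) and ASO-NEAT1-1473 (181.2, 204.5 and 232). In ASO-NEAT1-1047 it stood at 243.8, 331.2 and 317.4 CPM. The interval counts such structure as spread. The exact permutation p over the libraries was 0.0119 for SFPQ and for NONO, the smallest these libraries allow, and 0.393 for NEAT1. With libraries exchanged only within a replicate number, the exact permutation p for NEAT1 was 0.37. A fall of NEAT1 was thus not called in these counts, and those groups are called the libraries labelled ASO-NEAT1 throughout. The counts hold 1 value per gene from poly(A)-selected RNA, so they do not tell transcripts of NEAT1 apart, here or below.

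The paraspeckle genes also moved with each other. After SFPQ knockdown NONO rose by 0.52 (SE 0.07, adjusted p = 5.13e-07), PSPC1, the third paralog of the family, by 0.68 (SE 0.07, adjusted p = 4.22e-09), and NEAT1 by 1.06 (SE 0.22, adjusted p = 0.000261), from 309.3 ± 106 CPM to 643.5 ± 161 and 650.8 ± 129. After NONO knockdown PSPC1 rose by 0.71 (SE 0.07, adjusted p = 1.19e-07) and SFPQ by 0.34 (SE 0.09, adjusted p = 0.011), which missed the threshold with siNONO-3 alone (adjusted p = 0.0572) and without siCtrl replicate 2 (adjusted p = 0.0556) or 3 (adjusted p = 0.0512). NEAT1 had a log2 fold change of 0.07 there (adjusted p = 0.869). The NEAT1 difference between the SFPQ and NONO effects was 1.00 (adjusted p = 3.55e-05), while that of PSPC1 was -0.02 (95% interval -0.141 to 0.098). In the libraries labelled ASO-NEAT1, SFPQ, NONO and PSPC1 had log2 fold changes of -0.02, -0.05 and -0.06 (adjusted p = 1 each).

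**Figure D1:**
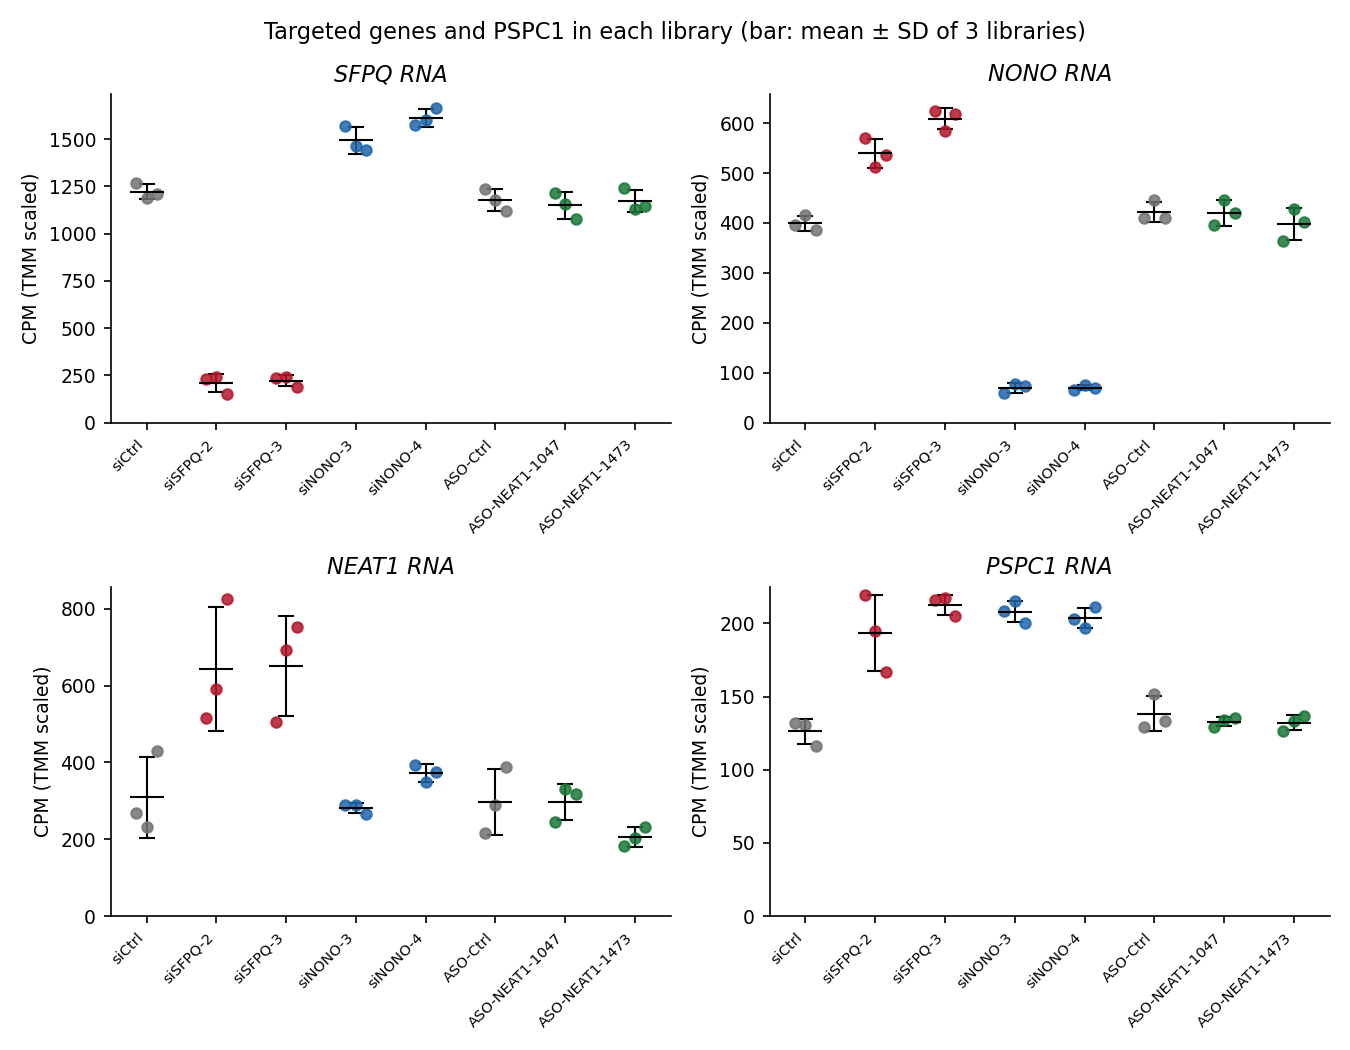
CPM of SFPQ, NONO, NEAT1 and PSPC1 in each of the 24 libraries (points) by group, with the mean and SD of 3 libraries. SFPQ averaged 207.6 and 222.5 CPM and NONO 69.23 and 70.07 CPM in their own knockdown libraries, while NEAT1 averaged 297.2, 297.4 and 205.9 CPM across the ASO groups.

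SFPQ knockdown changed most of the transcriptome. Genes nearly silent in the control were switched on: LRRN3, a neuronal membrane protein, had 1576 reads in the 6 siSFPQ libraries against 2 in siCtrl, a ratio of 592 (counting interval 164 to 4890), and LCK, a kinase of T cells, had 593 against 1, a ratio of 445 (79.6 to 17600). KRT20, an intestinal keratin, rose from 0.136 CPM to 21.9 and 26.2, and TFPI, an inhibitor of coagulation, from 0.132 to 23.7 and 23.4. LPAR6, a lysophosphatidic acid receptor gene, had a ratio of 276 (76 to 2280). LPAR6 overlaps RB1 and LRRN3 overlaps IMMP2L on the other strand, so their reads are uncertain in part. DKK4, a secreted Wnt antagonist, had 215 reads against 0, at least 53.8-fold higher, and the noncoding RNA MROCKI was at least 72.1-fold higher. AADAC, AADACP1 and FAM172BP, at least 49.8-, 87.8- and 51.6-fold higher, are related genes or pseudogenes whose reads are uncertain.

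GRIK1, a kainate receptor subunit, fell from 133 ± 18.1 CPM to 4.49 and 3.42, a log2 fold change of -5.08 (SE 0.13, adjusted p = 3.68e-22); it overlaps BACH1 on the other strand. NEGR1 and OPCML, cell adhesion molecules of neurons, had log2 fold changes of -5.73 and -4.83. GALNT13, PPM1E, HS6ST3, RAB3C, ST6GALNAC3 and COLEC12 fell as well, with log2 fold changes of -5.79, -5.48, -4.83, -4.74, -4.55 and -4.55. TMEM26, which spans 46.7 kb, fell by 5.59. PPM1E overlaps TRIM37, NEGR1 overlaps ZRANB2-DT, OPCML and RAB3C overlap noncoding genes and TMEM26 overlaps TMEM26-AS1, so their values are uncertain in part. In all, 11177 of 15869 genes tested (70.43%) were called, 5499 higher and 5678 lower, of which 2806 and 2364 changed at least 2-fold. TMM scaling takes most genes as unchanged, which these counts cannot check with so many called. The balance of directions turned with the scaling: RLE factors gave 5702 higher and 5490 lower, and upper quartile factors 5337 and 5855. Each siRNA alone called 10293 (siSFPQ-2) and 10629 (siSFPQ-3), and 8857 were called in the same direction with both against 3447.1 for independent lists, with 64 in opposite directions. The effects of the siRNAs correlated across genes with r = 0.94, against 0.409 for simulated unchanged groups that share controls, and their covariance was 2.0125 against a simulated 0.0602. The siSFPQ libraries also differed from siCtrl in measures of quality. Their total counts, all under 9999025, were lower, and mitochondrially encoded genes took 10.4 ± 0.893% against 8.211 ± 0.756% of the counts (exact permutation p = 0.0119 each, n = 6 and 3).

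Most genes spanning over 300 kb fell. Their 539 tested members had a median log2 fold change of -0.94 (interquartile range -2.253 to 0.479); 326 (60.5%) fell and 131 rose, and 255 (47.3%) fell at least 2-fold. ROBO2, an axon guidance receptor spanning 1743.3 kb, fell by 4.24 (SE 0.11) from 313 to 19.9 and 13.9 CPM, and LPP, which hosts a microRNA within 737.4 kb, fell by 3.39. The pattern had exceptions: EPHA5 (350.9 kb) and SEMA3A (536.9 kb) rose by 5.03 (SE 0.46) and 4.77 (SE 0.44). Shorter genes had medians near 0, at -0.04 for 100 to 300 kb and 0.09 for 30 to 100 kb. Over the fixed threshold of 100 kb, the difference in medians was -0.14 (exact permutation p = 0.0119, the smallest possible), and over 300 kb, a threshold chosen after the data were seen, it was -0.91 (exact permutation p = 0.0119). A threshold of 50 kb turned the sign (0.04, exact permutation p = 0.167), and exonic length in place of span gave 0.07 (exact permutation p = 0.0357). As siCtrl was the reference in every split, these permutation p-values lean low and are descriptive only.

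**Figure D2:**
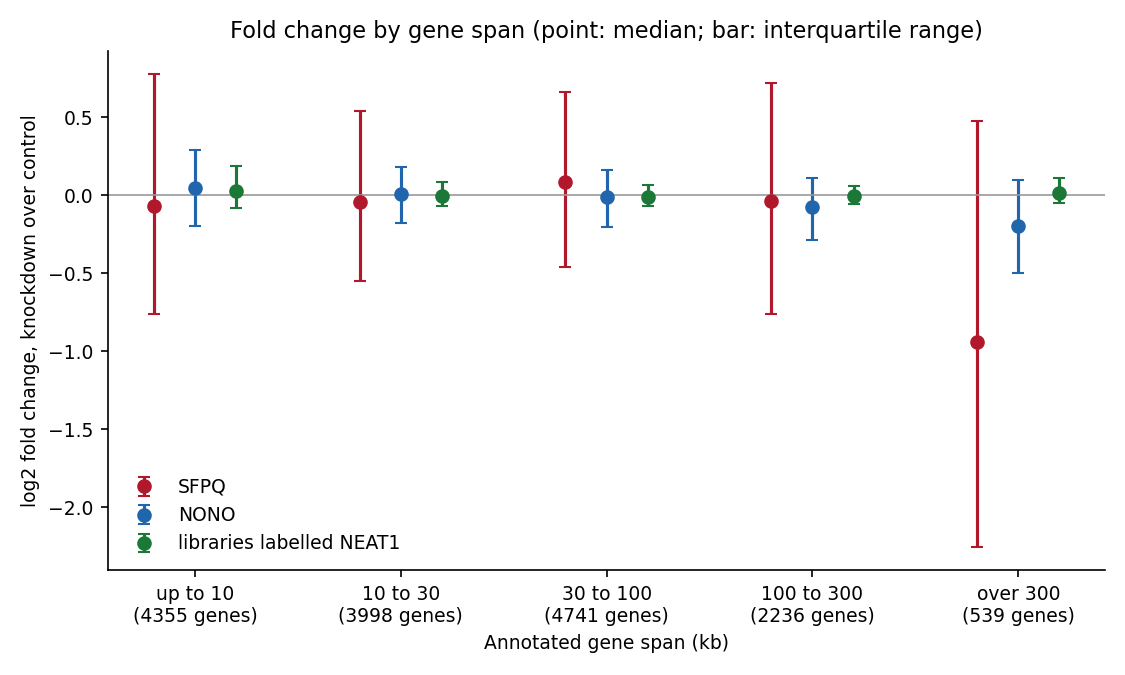
Median log2 fold change (points) and interquartile range (bars) of genes grouped by annotated span in kb, for the mean effect of each target's reagents. The group over 300 kb had medians of -0.94 for SFPQ, -0.20 for NONO and 0.02 for the libraries labelled ASO-NEAT1.

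Host genes of microRNAs went both ways after SFPQ knockdown. MIR17HG (chromosome 13, 91347820 to 91354579), the host of the oncogenic miR-17-92 cluster, fell from 93.9 ± 5.23 CPM to 25.5 ± 7.14 and 25 ± 0.304, a log2 fold change of -1.92 (SE 0.10, adjusted p = 5.79e-16). H19, an imprinted RNA that hosts miR-675, fell by 2.59 (SE 0.17), MIR210HG by 2.99 (SE 0.49), MIR497HG by 2.45 (SE 0.26) and FTX, which spans 353.1 kb, by 1.73 (SE 0.12). MIRLET7IHG rose by 1.92 (SE 0.15), from 13.5 to 47.5 and 55.9 CPM. MIR181A1HG had 131 reads against 0 in siCtrl, at least 32.8-fold higher, and MIR302CHG had a ratio of 15.5 (5.07 to 77.3). MIR302CHG overlaps LARP7, FTX overlaps JPX, MIR497HG overlaps C17orf49 and MIRLET7IHG an unnamed gene, so these hosts are uncertain in part. Of 40 noncoding hosts measured, 16 rose and 17 fell, the same counts when adjusted over the list alone; their median was -0.07, their mean 0.14, and camera gave a downward direction (adjusted p = 0.743). MIR34AHG, LINC-PINT, MIR503HG and MIRLET7A1HG were among those not called, with log2 fold changes of 0.07, 0.34, 0.54 and -0.20.

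Of 48 protein-coding hosts measured, 26 fell and 13 rose (also adjusted over the list alone), with LPP and TENM4 (log2 fold changes -3.39 and -3.84) among the falls and VMP1, the host of miR-21, rising by 1.66 (SE 0.11) from 102 to 295 and 350 CPM. The camera adjusted p was 0.00155, and the adjusted p = 0.0769 with an estimated correlation. The microRNA processing machinery had 7 genes higher and 19 lower of 34 (camera adjusted p = 0.159): LIN28B, which blocks let-7 maturation, fell by 1.66 (SE 0.08), TNRC6C by 1.08, and the terminal uridylyltransferases TUT7 and TUT4 rose by 1.32 and 0.91. Of 30 paraspeckle proteins 7 rose, RBM7 by 0.59, and 14 fell, the targeted gene and ZC3H6 (-1.37) among them (camera adjusted p = 0.236). VMP1 overlaps PTRH2, LIN28B overlaps LIN28B-AS1 and TNRC6C overlaps TMC6, so these too are uncertain in part.

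Of 37 S-phase genes 35 fell after SFPQ knockdown (1 rose), among them the replication helicase subunits GINS4, by 2.86 (SE 0.16), and GINS1, by 2.24 (SE 0.16); the median was -0.96, camera adjusted p = 1.44e-06 and adjusted p = 0.865 with an estimated correlation. Of 29 mitosis genes 24 fell, including BUB1 (-1.27) and HMMR (-1.20), and 1 rose when adjusted over the list alone (camera adjusted p = 0.000384; adjusted p = 0.865 with an estimated correlation). Double-strand break repair genes fell in 29 and rose in 9 of 44, 30 and 9 adjusted over the list alone, with XRCC3, which overlaps KLC1 and is uncertain, at -2.31 and RBBP8 at 0.92 (camera adjusted p = 0.045; adjusted p = 0.865 with an estimated correlation). The siRNAs differed in this respect: the S-phase median was -1.39 with siSFPQ-2, where 36 of 37 fell, and -0.57 with siSFPQ-3, where 22 fell and 2 rose. For mitosis genes the medians were -1.15 and -0.39. Camera called both differences between the siRNAs (adjusted p = 1.19e-26 for S-phase and 6.07e-31 for mitosis genes). Neither was called with an estimated correlation (camera adjusted p = 0.214 and 0.202). The mitochondrial share of counts was 10.916 ± 1.055% with siSFPQ-2 and 9.878 ± 0.269% with siSFPQ-3.

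Stress lists went different ways after SFPQ knockdown. Of 27 p53 target genes 21 rose and 1 fell, with a median of 0.81: CDKN1A, the cell cycle inhibitor p21, by 1.69 (SE 0.14), the p53 antagonist MDM2 by 0.81 (SE 0.10), PLK3 by 2.48 and the pro-apoptotic BBC3 by 2.24, while TRIAP1 fell by 0.74 (camera adjusted p = 0.000361; adjusted p = 0.61 with an estimated correlation). Of 18 NF-kB target genes 15 rose and 1, TNFAIP2, fell by 0.82; the cytokine IL1B had a read ratio of 81.1 (27.5 to 395) and the chemokine CCL20 of 21 (6.95 to 104). The list's median was 1.76, also with its low-count members at their bound (camera adjusted p = 1.44e-06; adjusted p = 0.099 with an estimated correlation). Interferon-stimulated genes split: 15 of 24 rose, ISG20 by 3.41, and 5 fell, IFIT1 from 647 to 86.3 and 68.7 CPM (camera adjusted p = 0.429). In the integrated stress response 8 of 22 rose, the cystine transporter SLC7A11 by 3.92 (SE 0.63), and 10 fell, PSAT1 by 1.99 (camera adjusted p = 0.922). Endoplasmic reticulum chaperones fell in 11 and rose in 3 of 17, EDEM1 by 2.32 upward and SDF2L1 at -2.13 (camera adjusted p = 0.142).

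Of 25 non-neuroendocrine and mesenchymal genes 17 rose after SFPQ knockdown and 3 fell (17 and 5 adjusted over the list alone), ANXA1 from 6.13 to 163 and 208 CPM and CAV1 by 4.64 (SE 0.62), while SNAI2 fell by 1.94 (camera adjusted p = 0.00155; adjusted p = 0.243 with an estimated correlation). Of 33 extracellular matrix and adhesion genes 22 rose, the collagen receptor subunit ITGA2 from 15.5 to 266 and 345 CPM, and 5 fell, among them COL18A1 (-2.31; camera adjusted p = 0.00277; adjusted p = 0.481 with an estimated correlation). Cholesterol synthesis genes rose in 15 and fell in 4 of 24, HMGCS1 by 1.63 upward (camera adjusted p = 0.0738), though the replicate block called this list. Glycolysis and hypoxia genes rose in 10 and fell in 15 of 33, SLC2A3 at 4.87 and HK2 at -2.19 (camera adjusted p = 0.347). Neuroendocrine genes rose in 3 and fell in 4 of 11, with SYP at 1.52 and SNAP25 at -2.90 (median 0.03, mean -0.25, camera downward with adjusted p = 0.768). Synaptic genes rose in 11 and fell in 4 of 19, 11 and 5 adjusted over the list alone (camera adjusted p = 0.743), and markers of other cell types rose in 2, LYZ and PECAM1, and fell in 1, TP63, of 6 (median 0.64, camera downward with adjusted p = 0.51).

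The remaining lists were divided after SFPQ knockdown. Mitochondrially encoded mRNAs rose in 5 of 13, MT-ND4 by 0.47, and MT-ND6 fell by 0.68 (camera adjusted p = 0.429). Polyadenylation factors rose in 8 and fell in 8 of 25, XRN2 at 0.83 and CPSF1 at -1.17 (median -0.02, camera upward with adjusted p = 0.981). Exosome and decay factors rose in 7 and fell in 13 of 29, XRN1 at 0.94 and MPHOSPH6 at -1.30 (camera adjusted p = 0.429). Core histone genes rose in 11 and fell in 12 of 43, 11 and 11 adjusted over the list alone (median -0.06, camera upward with adjusted p = 0.907). For every list without such a count, the counts adjusted over the list alone were the same.

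Of 27 p53 target genes 26 rose after NONO knockdown and 0 fell, 26 also adjusted over the list alone: CDKN1A by 1.83 (SE 0.14), MDM2 by 1.02 (SE 0.10), the death receptor FAS (adjusted p = 0.000997), which overlaps ACTA2 and is uncertain in part, BTG2 by 1.88 (SE 0.13) and GDF15 by 1.93 (SE 0.24). The median was 0.99, with 1.16 for siNONO-3 and 0.81 for siNONO-4 (camera adjusted p = 8.42e-47; adjusted p = 0.0015 with an estimated correlation, the 1 NONO list to keep its call). NF-kB target genes rose in 9 of 18 (10 adjusted over the list alone), IER3 by 2.09 (camera adjusted p = 1.44e-06; adjusted p = 0.099 with an estimated correlation). The largest rises were NECTIN4, an adhesion molecule, by 2.89 (SE 0.24), the chemokine PPBP by 2.76, ABCA12 by 2.52, TRIM22 by 2.43, INPP5D by 2.12, LNCAROD by 2.08, CPA4 by 2.06 (from 142 to 604 and 577 CPM) and COL1A2 by 1.97. ZNF876P, a pseudogene whose reads are uncertain, fell by 3.15. TMEM26, ANO3, BCO1, RIMKLA, LRRC31, AMIGO2, GRIK1 and KBTBD11 fell too, with log2 fold changes of -3.13, -2.43, -2.37, -2.30, -2.13, -1.99, -1.96 and -1.91.

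Cholesterol synthesis genes fell after NONO knockdown in 6 of 24, 11 adjusted over the list alone (camera adjusted p = 0.000343, and 0.858 with an estimated correlation). This list was also lower in ASO-Ctrl than in siCtrl (median -0.14, camera adjusted p = 0.00644, and 0.943 with an estimated correlation). Glycolysis and hypoxia genes fell in 7 and rose in 1 of 33, NDRG1 falling by 1.08 (camera adjusted p = 0.000938; adjusted p = 0.61 with an estimated correlation). Extracellular matrix genes fell in 10 and rose in 3 of 33, 10 and 4 adjusted over the list alone (camera adjusted p = 0.0441, and 0.858 with an estimated correlation). The replicate block also ended this call. Mitosis genes fell in 6 of 29, 7 adjusted over the list alone (camera adjusted p = 0.00567; adjusted p = 0.865 with an estimated correlation), while core histone genes rose in 5 of 43, H2AC6 by 0.90 (camera adjusted p = 0.0267; adjusted p = 0.865 with an estimated correlation). Protein-coding microRNA hosts fell in 14 and rose in 6 of 48, RNF130 at -0.92 and FAM172A at -0.81 (camera adjusted p = 0.0289; adjusted p = 0.184 with an estimated correlation). Noncoding hosts rose in 5 and fell in 4 of 40: PVT1 rose by 1.14 (SE 0.17), MIR34AHG, a p53-responsive host that overlaps LNCTAM34A and is uncertain, by 0.86 (SE 0.11), and FTX fell by 0.77 (SE 0.11) (median -0.09, -0.11 with low-count members at their bound, camera upward with adjusted p = 0.967).

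The remaining lists were not called by camera in the NONO contrast. S-phase genes had 1 of 37 lower, 0 adjusted over the list alone (camera adjusted p = 0.0963), though the replicate block called this list. Neuroendocrine genes had 1 higher, NEUROD1 at 1.19, and 4 lower, 6 adjusted over the list alone, PCSK1 at -1.70 and CHGB at -1.62 (camera adjusted p = 0.0963). Paraspeckle proteins rose in 4 and fell in 2 of 30, 4 and 3 adjusted over the list alone (camera adjusted p = 0.282), and the microRNA processing machinery fell in 2 of 34, 0 adjusted over the list alone (camera adjusted p = 0.898). Non-neuroendocrine genes rose in 5 and fell in 3 of 25, 6 and 3 adjusted over the list alone (camera adjusted p = 0.272), and interferon-stimulated genes rose in 1 and fell in 1 of 24, 1 and 0 adjusted over the list alone (camera adjusted p = 0.419). Synaptic genes rose in 2 and fell in 3 of 19, integrated stress response genes in 2 and 2 of 22, and double-strand break repair genes in 1 and 2 of 44 (camera adjusted p = 0.142, 0.898 and 0.365). Chaperones fell in 3 of 17, and markers of other cell types rose in 1 and fell in 1 of 6 (camera adjusted p = 0.259 and 0.419). Mitochondrially encoded mRNAs rose in 2 of 13, polyadenylation factors in 1 of 25 and exosome and decay factors in 2 of 29 (camera adjusted p = 0.16, 0.225 and 0.295). For every list without a count adjusted over the list alone, the counts were the same. Among the other genes named here, RBM7, TUT4, LPP, IFIT1, GINS4, ITGA2, COL18A1, EPHA5, MT-ND4, CPSF1, LINC-PINT, ABCA12, TRIM22, IER3, COL1A2, AMIGO2, FAM172A, NEUROD1, MDM2 and SLC14A2 also overlap a tested gene and are uncertain in part.

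In total NONO knockdown called 2767 genes (17.44%), 1186 higher and 1581 lower, of which 254 and 263 changed at least 2-fold. siNONO-3 alone called 3165 and siNONO-4 1752, and 961 were called the same way with both, against 176 for independent lists, with 25 in opposite directions. The siRNAs' effects had r = 0.616 across genes, against 0.468 for simulated groups sharing controls, and a covariance of 0.201 against 0.0599. Genes over 300 kb had a median of -0.20, and 131 of 539 (24.3%) fell, ROBO2 by 0.98 (SE 0.09). The difference of medians over 100 kb was -0.10 (exact permutation p = 0.0119). With siCtrl as the reference in every split, this p leans low and does not establish so small a difference. Without siCtrl replicate 1 the total was 1661 and the count with both siRNAs 534, and without siNONO-4 replicate 3 the latter was 579. With the replicate number as a block, both the total and the count with both siRNAs were higher, as given in the closing section.

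No gene was called in the libraries labelled ASO-NEAT1. edgeR gave 0 genes in the mean contrast and with either ASO alone, and DESeq2 also gave 0. At an unadjusted edgeR p under 0.05 there were 353, 365 and 424 genes, where chance gives 793.5. So few small p-values point to a cautious test in this contrast, and 0 calls are weak evidence of no change. Without ASO-Ctrl replicate 3 the count of called genes was 19. MIR17HG stood at 90.8 ± 2.84, 100 ± 7.17 and 103 ± 8.55 CPM in ASO-Ctrl and the libraries labelled ASO-NEAT1-1047 and ASO-NEAT1-1473 (log2 fold change 0.16, adjusted p = 1). No list had a called member; camera gave core histone genes upward (median 0.31, adjusted p = 2.32e-14; adjusted p = 0.184 with an estimated correlation), mitochondrially encoded mRNAs downward (median -0.10, adjusted p = 0.000102; adjusted p = 0.61 with an estimated correlation) and noncoding host genes upward (median 0.09, 0.08 with low-count members at their bound, adjusted p = 0.0138; adjusted p = 0.481 with an estimated correlation). Core histone genes and mitochondrially encoded mRNAs also differed between the controls, in the other direction: ASO-Ctrl minus siCtrl had medians of -0.24 and 0.16 (camera adjusted p = 0.0464 and 6.9e-05; adjusted p = 0.943 each with an estimated correlation). The long-gene difference was -0.01 (exact permutation p = 0.881). Since NEAT1 RNA itself was not called lower, these values describe the labelled libraries rather than a known loss of NEAT1.

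The SFPQ and NONO effects were compared directly. MIR17HG differed by -1.84 (adjusted p = 5.27e-17), with a NONO effect of -0.09, and H19 by -3.21 (adjusted p = 6.2e-17), as it rose by 0.62 (SE 0.14) after NONO knockdown. MIRLET7IHG differed by 2.50 (adjusted p = 1.63e-16), having fallen by 0.58 (SE 0.15) after NONO knockdown, a call lost without siCtrl replicate 3 (adjusted p = 0.0892), and MIR34AHG by -0.79 (adjusted p = 4.87e-09). Among all genes, LRRN3, LCK and MROCKI were highest in the SFPQ effect relative to NONO, while PRR9 (adjusted p = 0.000149), SLC14A2 (4.21e-05) and EGFL6 (3.77e-06) were lowest, PRR9 averaging 2.23 CPM in siCtrl, 0.165 and 0.281 with the SFPQ siRNAs and 9.58 and 8.92 with the NONO siRNAs, SLC14A2 3.24, 0.188 and 0.121, and 5.88 and 9, and EGFL6 9.03 CPM in siCtrl, 0.949 and 0.441 with the SFPQ siRNAs and 17.3 and 35 with the NONO siRNAs. S-phase genes were lower with SFPQ than NONO knockdown (median -0.77, camera adjusted p = 9.86e-05), NF-kB targets higher (1.56, 0.000607), matrix genes higher (1.36, 0.000124) and cholesterol synthesis genes higher (1.00, 0.00147). Mitosis genes (-0.61, 0.01) and protein-coding microRNA hosts (-0.28, 0.0252) were lower and non-neuroendocrine genes higher (0.88, 0.00312). None of these kept its call (adjusted p = 0.827, 0.173, 0.173, 0.827, 0.897, 0.173 and 0.173 with an estimated correlation, in this order). The p53 list differed by a median of -0.14 (camera adjusted p = 0.621).

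**Figure D3:**
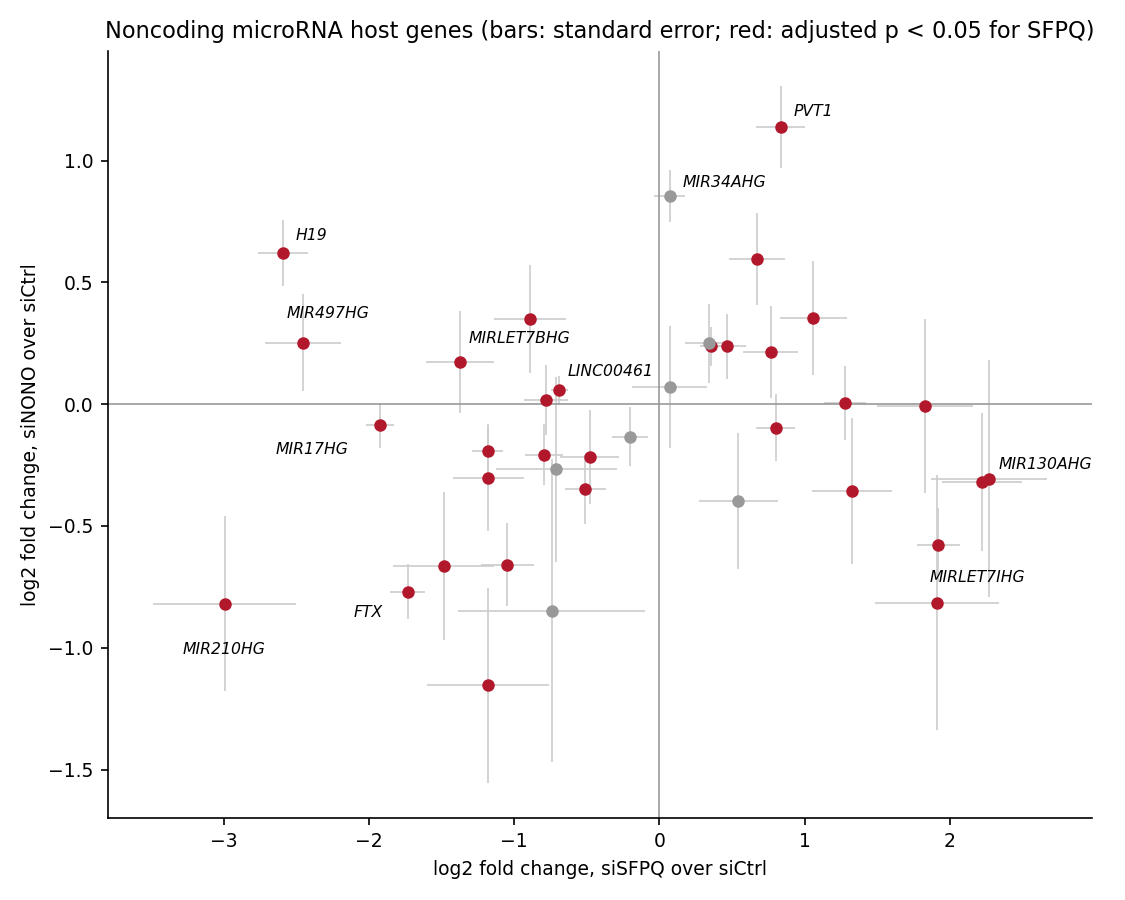
Log2 fold change of 38 noncoding microRNA host genes after SFPQ (horizontal axis) and NONO knockdown (vertical axis) with standard errors; the 2 hosts with 3 or fewer control reads are left out. MIR17HG lies at -1.92 and -0.09, H19 at -2.59 and 0.62, and FTX at -1.73 and -0.77.

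**Figure D4:**
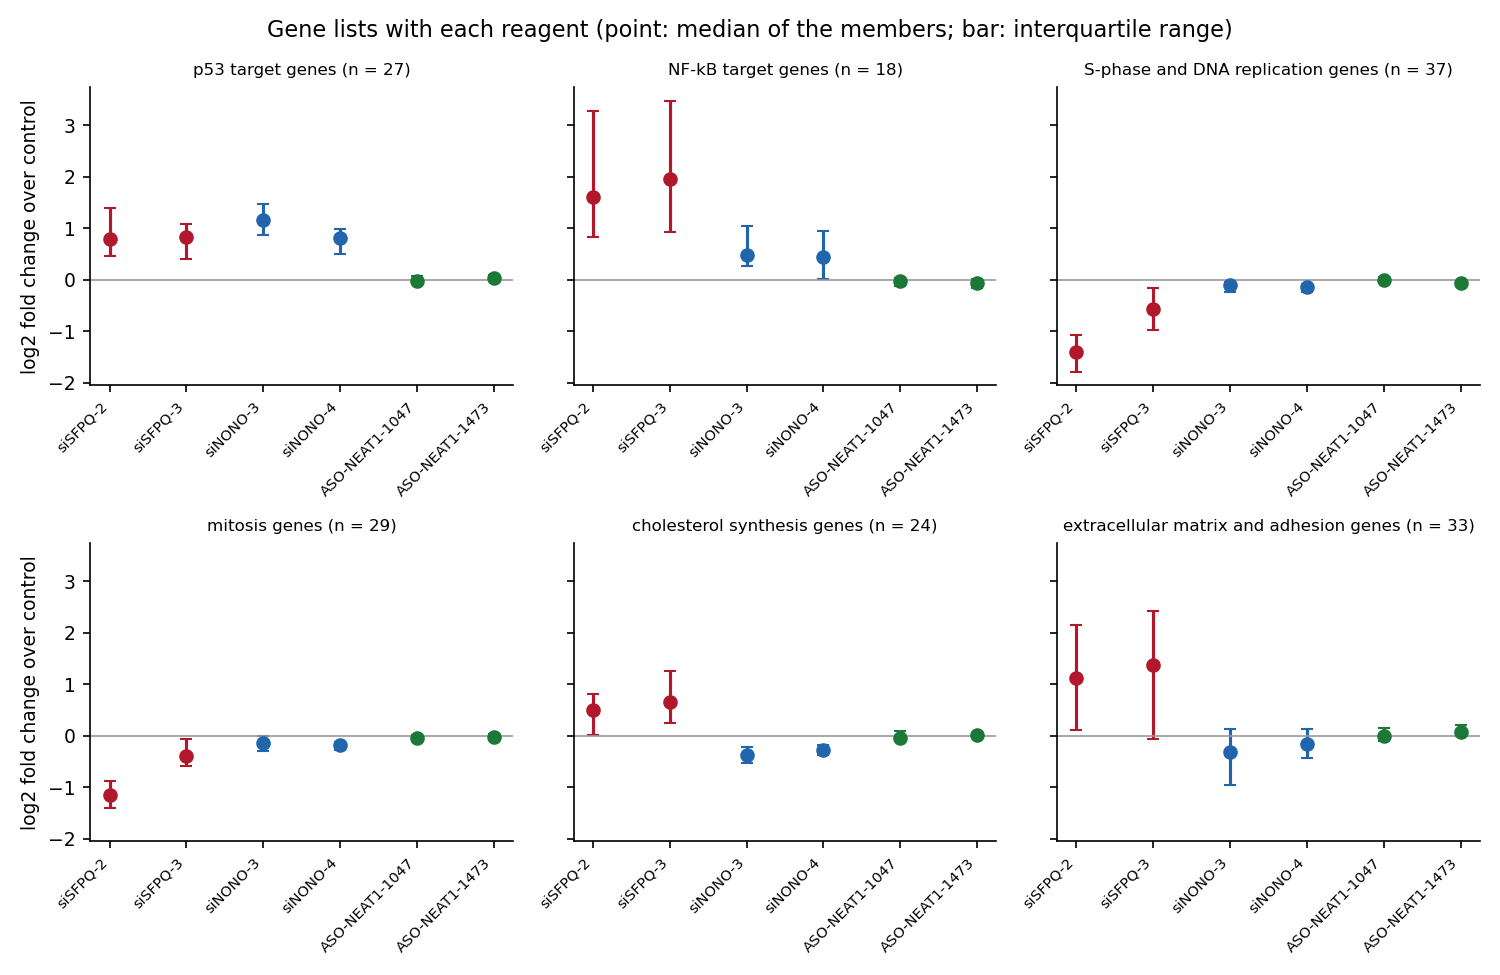
Median log2 fold change (points) and interquartile range (bars) of 6 gene lists for each of the 6 reagents against its own control. The p53 list had medians of 0.79, 0.83, 1.16 and 0.81 with the SFPQ and NONO siRNAs, and S-phase genes -1.39, -0.57, -0.10 and -0.14.

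The effects of SFPQ and NONO knockdown differed at 11958 genes. They shared 1296 calls in the same direction, 561 higher (411 for independent lists) and 735 lower (565.7), and had 830 in opposite directions, 517 higher with SFPQ and lower with NONO knockdown (547.9 for independent lists) and 313 the other way (424.4). Simulated groups sharing controls held no changed genes, so their count of at most 0 shared calls says nothing on this overlap. The covariance was 0.1444 against a simulated 0.0602, and r was 0.194 across genes against a simulated 0.609. With 3 siCtrl libraries the controls could not be split, so part of the excess may come from them. Without siCtrl replicate 1 the shared calls numbered 819. The SFPQ effect differed from that in the libraries labelled ASO-NEAT1 at 9203 genes, with IL7R, LPAR6 and AADACP1 highest and TMEM26, GLDN and GALNT13 lowest, and MIR17HG by -2.09 (adjusted p = 6.14e-13). The AADACP1 call was lost without ASO-Ctrl replicate 3 (adjusted p = 1). The NONO effect differed at 1026, with PLK2, a p53-responsive kinase gene, higher by 3.91 (SE 0.58), NECTIN4 by 3.05, PPBP by 2.93, TMEM26 at -3.27 and ZNF876P at -2.93; p53 targets differed by a median of 0.98 (camera adjusted p = 1.05e-43; adjusted p = 0.000764 with an estimated correlation) and NF-kB targets by 0.42 (camera adjusted p = 1.61e-07; adjusted p = 0.037 with an estimated correlation), and no other list called there kept its call with an estimated correlation. That count was 607 without siCtrl replicate 1 and 575 without ASO-Ctrl replicate 2. With 0 genes called there by edgeR and by DESeq2, no calls were shared between either siRNA target and the libraries labelled ASO-NEAT1, against 13 for SFPQ and 5 for NONO without ASO-Ctrl replicate 3. The controls themselves, ASO-Ctrl against siCtrl, differed at 72 genes, 19 higher and 53 lower. This count was 42 and 24 without siCtrl replicates 1 and 3, and 33 and 21 without ASO-Ctrl replicates 1 and 2. With the replicate number as a block it was higher, as given in the closing section. So were the calls shared by SFPQ and NONO and the count of NONO against ASO-NEAT1.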

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

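The tests over 300 kb, and those of whether NEAT1 had enough reads or too wide a spread, of exchanged ASO libraries, of 1 NONO siRNA acting off target and of a response to any effective siRNA were chosen only after the results were seen.

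The reagents of 1 target differed from each other by a direct test. siSFPQ-2 and siSFPQ-3 differed at 2328 genes, 962 higher and 1366 lower with siSFPQ-2 (edgeR), 1495 without siSFPQ-2 replicate 3, and S-phase genes lay lower with siSFPQ-2 by a median of -0.877, at 30 of 37 members (camera adjusted p = 1.19e-26; adjusted p = 0.214 with an estimated correlation). So did mitosis (-0.795), double-strand break repair (-0.363), cholesterol synthesis (-0.206) and paraspeckle genes (-0.152), with camera adjusted p = 6.07e-31, 1.18e-09, 0.0228 and 0.00601, and 0.202, 0.451, 0.776 and 0.588 with an estimated correlation. siNONO-3 and siNONO-4 differed at 1590 genes, 747 higher and 843 lower with siNONO-3. With siNONO-3 p53 target genes were higher by a median of 0.319 (12 of 27 higher, 1 lower), integrated stress response genes higher by 0.547 and interferon-stimulated genes at -0.352 (camera adjusted p = 3.01e-08, 5.4e-05 and 0.0022; 0.288, 0.917 and 0.288 with an estimated correlation). Leaving out siNONO-3 replicate 2 or 3 gave 1019 and 951, and leaving out siNONO-4 replicate 1 or 3 gave 1029 and 1021. For these pairs 10 splits of 6 libraries are too few for a share under 0.05; the real counts in a simpler fit were 1690 and 1482, and the highest of the other splits 0 and 0. The ASO pair gave 0 against 1 and the control pair 35 against 0, also of 10 splits.

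Other splits of the same libraries were counted with that simpler fit. No other split called as many genes for SFPQ knockdown (9727, 1 of 84 splits as large, highest other 108, which set the siSFPQ-2 libraries against the rest). The same held for NONO knockdown (1489, 1 of 84, highest other 1263, which set the siNONO-3 libraries against the rest). With both reagents it held for SFPQ (8330, 1 of 60 drawn splits, highest other 2) and NONO (999, 1 of 60, highest other 497). These shares speak only to a chance division of these libraries, as the replicates may not be separate cultures. For the libraries labelled ASO-NEAT1 the real split gave 0 genes, which every split matches (84 of 84, the highest 1565), so this count decides nothing; the highest set the replicate 1 libraries against the rest, which points to a structure of the samples. The same holds with both ASOs (60 of 60, the highest 301). For SFPQ against NONO the count was 10081 (1 of 60; highest other 0), for SFPQ against the libraries labelled ASO-NEAT1 8442 (1 of 60; highest other 8419), for NONO against them 589 (2 of 60; highest other 874; these highest others kept siCtrl as the control and regrouped the ASO arm), and for calls shared by SFPQ and NONO 551 (1 of 60; highest other 34).

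Most genes spanning over 300 kb fell after SFPQ knockdown. Low read counts are argued against, as the difference from shorter genes of like expression was -0.91. GC content and exonic length are argued against as the whole cause, as the median was -0.993 after both trends were removed. An off-target effect of 1 siRNA is argued against, as the weakest of the 6 siSFPQ libraries still gave -0.748. A dependence of very long genes on SFPQ therefore stays as a hypothesis, found and tested on the same data, and the lower depth and higher mitochondrial share of the siSFPQ libraries go with it.

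NEAT1 RNA was not called lower in the libraries labelled ASO-NEAT1. Too few reads are argued against, as the counting interval of ASO-NEAT1-1473 against ASO-Ctrl (7769 and 10565 reads) ended at -0.537. A 2-fold fall hidden by the spread between libraries is argued against for the mean and for ASO-NEAT1-1047, whose intervals ended at -0.693 and -0.497, but stays open for ASO-NEAT1-1473, where the interval reached -1.031. The interval of NEAT1 in ASO-Ctrl minus siCtrl ended at -0.561, which argues against a 2-fold fall of NEAT1 in the libraries labelled ASO-Ctrl. It cannot decide whether ASO-NEAT1 and ASO-Ctrl libraries were exchanged. NEAT1 averaged 297.2 CPM in ASO-Ctrl and 297.4 in ASO-NEAT1-1047, so exchanging these would hardly move it. Fragments 3-prime of an ASO cut, where they carry a poly(A) tail, could leave the count high. As gene counts hold no position or transcript, this cannot be told apart from a lack of knockdown. The measured value was -0.263, which ran from -0.451 without ASO-Ctrl replicate 1 to -0.032 without ASO-Ctrl replicate 3.

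The p53 target genes rose after NONO knockdown. Low levels in siCtrl are argued against, as the list's median in ASO-Ctrl minus siCtrl was 0.053, and an off-target effect of 1 siRNA is argued against, as the weaker siRNA gave a median of 0.811. A response to any effective siRNA cannot be told apart from one to the loss of these proteins. The median of the NONO minus SFPQ difference was 0.142, but 9 of 27 members were higher and 11 lower after SFPQ than after NONO knockdown, so it decides nothing, and the design has no effective siRNA against an unrelated gene.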

How the results depend on the processing

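The 300 kb length threshold, with its matched and protein-coding forms, was chosen only after the data were seen. Targeted genes kept their direction and call, and totals their size within 1.5 times, except as given here. Gene lists were rerun only with an estimated correlation, with 1 CPM in 3 libraries and with the replicate block. There they kept their direction and call except as given here. The cause of a change was not tested unless stated. A 2-fold minimum, which calls fewer genes by construction, gave 5170 for SFPQ, 4055 with both siRNAs, 517 for NONO and 208 with both. One group of 6 gave 1451 for NONO and siNONO-4 alone 1752. Without the filter the libraries labelled ASO-NEAT1 gave 3 genes, their reagents differed at 2, and 2 calls each were shared with SFPQ and NONO; the controls differed at 153, and at 132 by DESeq2. Same-numbered libraries correlated from 0.008 to 0.211 (SFPQ), 0.068 to 0.271 (NONO) and 0.071 to 0.29 (ASO-NEAT1), over 0.1 in 4, 5 and 5 of 6 pairs. As not every pair passed 0.1, the numbers were not taken to pair the libraries. Yet 4, 6 and 6 of 6 correlated best with their own number, a hint from the data and not the design. Where the numbers do mark shared conditions, tests without the block count that structure as spread between libraries. The replicate block gave 4262 for NONO, 1787 with both siRNAs, 2199 for NONO against ASO-NEAT1, 1999 shared by SFPQ and NONO, 2733 between NONO siRNAs and 351 between controls. It also called cholesterol synthesis genes for SFPQ (adjusted p = 0.00303) and S-phase genes for NONO (0.0213), ended the call of matrix genes for NONO (0.0608), and in ASO-NEAT1 turned the direction of uncalled markers of other cell types (0.938) and polyadenylation factors (0.993). With an estimated correlation 0, 1 and 0 lists were called for SFPQ, NONO and ASO-NEAT1. The long-gene difference for SFPQ was 0.037 at 50 kb and 0.066 by exonic length; for NONO it was -0.037 by exonic length; for ASO-NEAT1, never called, it was 0.008 at 200 kb, 0.021 at 300 kb, 0.014 by exonic length, 0.002 for protein-coding genes, 0.004 at 5 CPM, 0.003 matched, and 0.014 and 0.029 at 300 kb matched and protein-coding. Leaving out 1 library gave 10742 to 11255 for SFPQ, 8372 to 8648 with both, 1661 to 2700 for NONO, 534 to 855 with both, 0 to 19 for ASO-NEAT1 (NEAT1 itself from -0.451 to -0.032), 0 to 13 with both, 575 to 1031 for NONO against ASO-NEAT1, 819 to 1370 shared by SFPQ and NONO, 0 to 13 and 0 to 5 shared with ASO-NEAT1, 1495 to 2137 between SFPQ siRNAs, 951 to 1332 between NONO siRNAs, 21 to 53 between controls, and -0.026 to 0.014 for the ASO-NEAT1 long-gene difference. Of 219 named-gene results with 4005 alternatives, 3861 stayed, 139 lost their call (110 with a library left out) and 5 uncalled values turned sign: NEAT1 after NONO knockdown (-0.025 and -0.101, with a range of -0.101 to 0.364), and in ASO-NEAT1 SFPQ (0.01 and 0, range -0.058 to 0.01) and PSPC1 (0.011, range -0.11 to 0.011).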

Other observations

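The tests of neighbouring genes were written down before their results were seen, on fold changes already described.

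Genes that rose more than 4-fold after SFPQ knockdown lay next to other risen genes. Of 1262 such genes, 537 overlapped no tested gene and had a tested neighbour within 50 kb. The nearest neighbour rose over 2-fold for 176 of them (32.8%), against 17.7% on average and at most 24.4% in 10000 shuffles of fold changes within chromosome and expression class (permutation p = 1e-04, the smallest the shuffles can give). Adjacent risen genes can each count as the neighbour of the other, which the shuffles did not keep, so this p may be too small. Among the neighbours of other genes the share was 13.3%. A spread of rises to neighbours may therefore be a hypothesis worth following, for example through transcripts that run on past a gene's end. The shuffles did not keep clusters of genes together, so neighbours that rise together for another reason would give the same excess. Whether transcripts run on stays open: same-strand neighbours downstream rose in 58 of 142 (40.8%) and upstream in 66 of 201 (32.8%), Fisher's exact p = 0.139, and those on the other strand in 52 of 194 (26.8%). A same-strand pair of risen genes can enter both the downstream and the upstream count, which draws these shares together.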
